A study of Mus musculus with 17 samples.

How the data were processed

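RNA polymerase II was immunoprecipitated from mouse bone marrow-derived macrophages and the recovered DNA was sequenced as 75 nt single-end reads on a NextSeq 500, per the labels' protocols. The 16 immunoprecipitated libraries formed 8 groups of 2, defined by genotype (WT or N4bp1 KO) and treatment (untreated, or R837 for 2, 4 or 6 h), as the sample titles and characteristics give them. An input DNA sample was also listed and was not used here. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

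Per the submitters' processing notes, GSNAP and MACS2 were used with the GRCm38 build. Their versions, the call threshold, the control and any scaling of depth were not given in the sources used here. Each deposited file was a list of 1 bp peak summits for 1 library, and replicates had not been pooled by the authors. The deposited score of each summit was −log10 of a p-value or q-value, and the files do not say which of these it was. The score is the authors' own and was used only to rank summits within a list. The files hold no read counts, so the read depth of each library is unknown and no interval for counting error can be given. The number of summits ranged from 8394 to 29760 per library, 298175 in all, and lowest scores lay between 7.03 and 7.09. All summits lay on the standard chromosomes, and no list was identical to another, since all differed in length. Codes in the deposited peak names fall into 3 series, 1 for the untreated and 2 h libraries, 1 for 4 h and 1 for 6 h. KO and WT were compared within a series, while 4 h and 6 h were compared with untreated libraries across series, and any batch between series cannot be separated from these times. Replicate 2 of KO at 6 h shared at most 0.087% of its score values with any other list, and its highest score was 563.5, against at most 320.4 elsewhere. Some other lists shared most score values, also across series. Replicate 1 of WT untreated shared 89.4% with replicate 1 of WT at 2 h and 87.2% with replicate 2 of WT at 6 h, against 41.3% with its own replicate. Replicate 2 of KO untreated shared 94.5% with replicate 1 of KO at 6 h. The cause of this sharing was not tested.

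Because ranks from lists of different lengths cannot be compared, each list was shortened to its 8394 best summits, the length of the shortest. For each of 21887 protein-coding genes, the region ran from 1 kb before to 1 kb after the annotated gene on GRCm38. The rank score of a gene was log2 of (8394 + 1) divided by the rank of its best summit, and 0 where none was in the shortened list. The highest possible rank score was 13.04. The plan had named the gene start with its strand, but the annotation used here gave no strand, so both gene ends were treated alike and the share of summits at promoters became the share within 1 kb of either gene end. Where a summit lay in more than 1 gene region it counted for each, and such genes are named with that remark.

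Genes with a summit in at least 2 of the 16 shortened lists were tested, 8474 in all. The rank scores were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group, a variance trend and empirical Bayes moderation, and p-values were adjusted by the Benjamini-Hochberg method over the genes of a contrast, with a threshold of 0.05. All 16 libraries entered 1 fit because each group held only 2. Contrasts set each treated group against the untreated group of its genotype, KO against WT at each time and over the 3 treated times, treated against untreated libraries over both genotypes, and the response in KO against that in WT. Each error printed after a change in rank score is the standard error (SE) of that fit. Fixed gene lists were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. The lists covered the NF-kB primary response, secondary cytokine and effector genes, interferon-stimulated genes, immediate early genes, negative feedback regulators, components of the TLR, IKK and caspase-8 pathways, macrophage identity, sterol synthesis, glycolysis, oxidative phosphorylation, cell cycle, ribosomal proteins, the unfolded protein response, NRF2 targets, lysosome and antigen presentation. A further 7 lists held markers of T and NK cells, B cells, neutrophils, dendritic cells, mast cells and basophils, erythroid cells, and fibroblasts and stroma. Some genes are in more than 1 list, so the list results are not independent. Tnfaip3 and Nfkbia are in the NF-kB and negative feedback lists, Il10 in the negative feedback and secondary cytokine lists, and Atf3 in the negative feedback and immediate early lists.

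List lengths, shares at gene ends and overlaps of summits within 500 bp were compared by exact permutation of the labels within times or genotypes, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Plots were drawn with matplotlib 3.10.9. The groups, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took the 12 largest rises and 8 largest falls that passed for R837 against untreated and for KO against WT over the treated times. For every other contrast it took the 5 largest rises and 3 largest falls whose libraries did not overlap, and it added passing list members and 10 fixed genes (N4bp1, Il1b, Il6, Tnf, Il12b, Csf3, Cxcl2, Nfkbia, Nos2 and Actb). If fewer genes passed, all of them were taken.

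The gene fits were tested on simulated lists with 200 changed genes and a noise SD of 0.74. That noise was independent between genes and had the same SD in every gene and library. Real genes and libraries differ in spread, so the recovery and call rates below need not hold for the real lists. For KO against WT with the gene numbers of the real libraries, 7.5%, 37.3% and 56.1% of genes shifted by 1, 2 and 3 on the log2 scale were recovered, and 1 of 8067 unchanged genes was called. For R837 against untreated, equal gene numbers gave 6%, 31.3% and 59.1% recovery with 6 of 4255 unchanged genes called. With the gene numbers of the real libraries, which were lower after R837, recovery was 28.4%, 61.2% and 95.5%, and 729 of 8118 unchanged genes were called, all of them lower. In the simulated permutation tests, 6% of 200 runs without a difference and 94.5% of runs with a difference of 2 SD fell below 0.05.

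Alternatives to each choice were computed. They were lists of the best 4197 summits, lists as deposited, the number of summits per gene (log2 after adding 0.5), a linear rank, gene ends only, regions extended by 3 kb, and 10 kb bins. Others were filters at 1 and 4 libraries, limma without the trend or with array weights, only the groups compared, a replicate block, presence of a summit by Fisher's exact test, and each library left out in turn. After the data were seen, further alternatives were added. In the first, genes were ranked by their best deposited summit and each library was shortened to its best 2693 genes, which gives each gene 1 rank and each library the same number of genes (5235 genes tested). Another left out replicate 2 of both 6 h groups, which held the shortest list and the list with unshared scores. A further one left the 6 h libraries out of the contrast of KO and WT, and gene lists were also tested under other gene measures.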

Results

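RNA polymerase II occupancy was mapped by chromatin immunoprecipitation and sequencing in mouse bone marrow-derived macrophages, which were wild type (WT) or lacked N4bp1 (knockout, KO). Cells were untreated or had received R837 (imiquimod, an agonist of the endosomal RNA sensor TLR7) for 2, 4 or 6 h, and each of the 8 groups held 2 libraries. N4BP1 is known as a suppressor of inflammatory cytokine production and a substrate of caspase-8, and the study's title places it in signalling through the IkB kinases. The comparisons address which genes carried polymerase after TLR7 stimulation and how this differed without N4bp1. Values are rank scores, the log2 position of a gene's best summit among the 8394 best summits of a library, from 0 (no summit) to 13.04 (the top summit). A rank score describes a gene's place within its list and is not an amount of polymerase. Read depth is unknown because the deposited lists hold no read counts.

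The targeted gene was examined first. N4bp1 (gene ID 80750, chromosome 8, 86841136 to 86885296 on GRCm38) held no summit in the shortened lists of the 4 untreated libraries. In WT macrophages its best summit stood at ranks 2446 and 947 at 2 h of R837, 2213 and 1280 at 4 h, and 3442 and 2699 at 6 h. In KO macrophages the ranks were 1588 and 537 at 2 h, 1713 and 775 at 4 h, and 1062 and 1122 at 6 h. N4bp1 rose after R837 by 2.54 ± 0.38 (SE, 12 against 4 libraries, adjusted p = 2.43e-04). The difference in N4bp1 between KO and WT was 0.72 ± 0.66 at 2 h (adjusted p = 1), 0.55 ± 0.66 at 4 h (adjusted p = 1) and 1.48 ± 0.66 at 6 h (adjusted p = 0.355), none of which passed. The labels do not say which part of N4bp1 was removed, so summits in the gene region of KO libraries do not check the genotype labels.

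The lists of polymerase summits were longer in KO than in WT macrophages after 4 and 6 h of R837. At 4 h the KO lists held 25612 and 24671 summits and the WT lists 16391 and 19710, and at 6 h they held 22157 and 29760 against 17007 and 8394. The 2 h lists were short in both genotypes, with 13825 and 9402 summits in KO and 10769 and 11010 in WT, and the untreated lists held 21439 and 22701 in KO and 24720 and 20607 in WT. Over all times the mean log2 list length was 0.41 higher in KO (two-sided exact permutation within times, p = 0.0370, 1296 relabellings). Leaving out 1 library in turn gave differences of 0.278 to 0.533. The call was lost for 11 of the 16 libraries, all but WT untreated replicate 1, KO untreated replicate 1, KO 2 h replicate 2, WT 4 h replicate 2 and WT 6 h replicate 1, with p up to 0.14 without KO 6 h replicate 2. The length of a list depends on depth and enrichment, which the files do not give.

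Polymerase summits lay at gene ends less often after R837. Among the 8394 best summits, 63.6% ± 1.3 (SD, n = 4) lay within 1 kb of a gene end in untreated macrophages and 45.0% ± 6.6 (SD, n = 12) after R837. The difference of −18.6 percentage points had p = 0.00128 (two-sided exact permutation within genotypes), the smallest value that the 784 relabellings can give. Treated lists ranged from 33.5% in replicate 2 of WT at 6 h to 58.4% in replicate 2 of KO at 6 h, above which all untreated lists lay (61.9% to 64.8%). With the lists as deposited the difference was −8.47 points (exact permutation, p = 0.00383), and replicate 1 of KO at 2 h (46.8%) lay within the untreated lists (42.8% to 48.1%). The share was 5.90 points higher in KO than in WT (two-sided exact permutation within times, p = 0.0309), but with the lists as deposited the difference was 0.459 points and the call was lost. It ranged from 4.14 to 7.65 points when 1 library was left out. The call was lost without WT untreated replicate 1 (5.58 points), WT 2 h replicate 1 (6.24) or 2 (5.55), KO 2 h replicate 1 (4.14), WT 6 h replicate 2 (4.5) and KO 6 h replicate 2 (4.47).

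**Figure D1:**
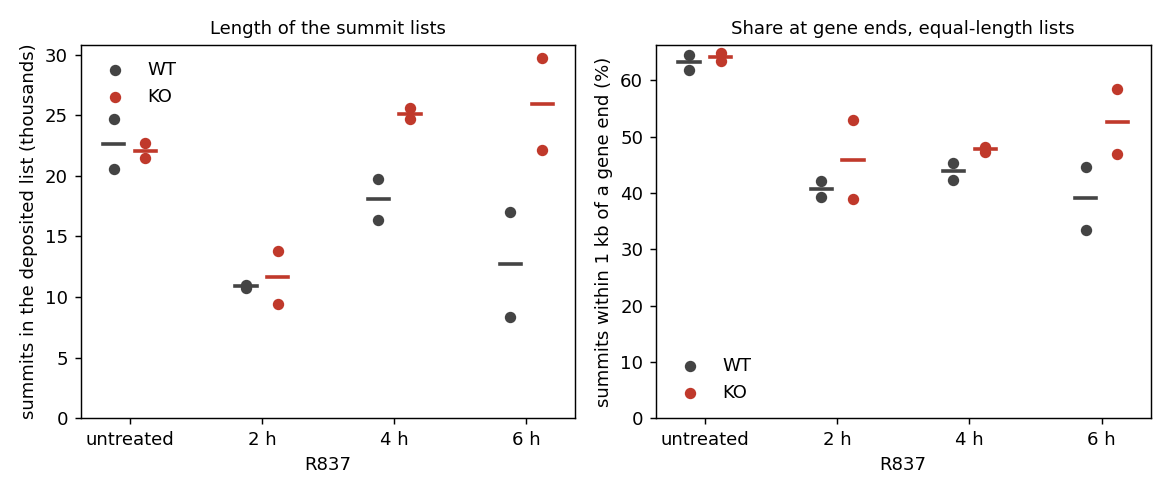
Summits per deposited list (left) and percent of the 8394 best summits within 1 kb of a gene end (right), against treatment, with 1 point per library and a bar at the mean of the 2 libraries of a group (WT grey, KO red). The 4 untreated lists lie between 61.9% and 64.8% at gene ends and the 12 treated lists between 33.5% and 58.4%.

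Averaged over all times, replicate lists shared more summits than lists of the other genotype. On average 61.4% of the summits in a replicate pair had a partner within 500 bp, against 58.2% between KO and WT lists of the same time. The difference of 3.16 points had p = 0.0123 (one-sided exact permutation), the smallest value the design allows. At no time did both replicate pairs stand above all pairs between genotypes at that time. The KO and WT replicate pairs shared 71.3% and 71.6% untreated (70.4% to 72.4% between genotypes) and 56.3% and 59.9% at 2 h (53.6% to 58.5%). At 4 h they shared 64.1% and 59.2% (54.3% to 59.7%), and at 6 h 55.1% and 53.6% (35.7% to 58.4%). The difference ranged from 1.75 to 3.84 points when 1 library was left out, and the call was lost without WT 6 h replicate 2 (1.75 points) or KO 6 h replicate 2 (1.92 points).

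R837 brought inflammatory genes to the top of the polymerase lists. Socs3, a feedback inhibitor of cytokine receptor signalling (gene ID 12702, chromosome 11, 117966079 to 117970336), had no summit in the shortened untreated lists and stood at ranks 5 to 19 in all 12 treated lists, a rise of 9.62 ± 0.37 (adjusted p = 6.15e-09). The neighbouring chemokine genes Ccl4 and Ccl3 rose by 9.21 ± 0.47 and 8.94 ± 0.47, although the best summit of Ccl4 also lay in the Ccl3 region in 6 of 16 libraries and that of Ccl3 in the Ccl4 region in 11. Tnf, the prototype inflammatory cytokine, rose by 6.30 ± 0.43, the chemokine gene Cxcl2 by 6.82 ± 0.45, and Il1b by 3.48 ± 0.49. Inhibitors of NF-kB signalling rose as well: Tnip3 by 6.45 ± 0.49, Tnfaip3 by 6.43 ± 0.36 and Nfkbia by 6.39 ± 0.49. Further large rises were those of Pde4b, a cyclic AMP phosphodiesterase (7.38 ± 0.44), Ehd1, which acts in endosomal recycling (7.29 ± 0.36), and the acute-phase gene Saa3 (7.20 ± 1.37, adjusted p = 0.00135, summit shared with Saal1 in 3 of 12 libraries). Best1 rose by 6.04 ± 2.15 (adjusted p = 0.0441), but its summit was that of Fth1, the ferritin heavy chain gene, in every library. The call of Best1 was lost without any of 13 of the 16 libraries (a change of 3.43 and adjusted p = 0.341 without replicate 2 of KO untreated) and when gene regions were extended by 3 kb (1.34, adjusted p = 0.0634). These changes set 12 treated against 4 untreated libraries over both genotypes. When summits in the gene region were counted instead of ranked, the change of Nfkbia was −0.33 (adjusted p = 0.009), and the rises of Tnf (0.18), Ccl3 (0.06) and Best1 (0.72) were not called.

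Several genes near the top of the untreated lists lost their place after R837. Zfp36l2, which encodes an RNA-binding protein that promotes mRNA decay (gene ID 12193, chromosome 17, 84183924 to 84187947), fell by 8.89 ± 0.42 (adjusted p = 4.16e-08), and Rgs2, a regulator of G protein signalling, fell by 7.80 ± 0.28. The chemokine receptor gene Cxcr4 fell by 6.63 ± 0.36, the lysosomal protease gene Ctsd by −6.20 ± 0.30, the myeloid transcription factor gene Cebpa by −6.14 ± 0.33 and the lipid receptor gene Trem2 by −5.89 ± 0.29. Fzr1 and Mfsd12, whose changes were −6.12 ± 0.35 and −5.99 ± 0.42, shared their best summit in 13 of 14 libraries. When summits were counted, the change of Ctsd was 1.60 (adjusted p = 1.88e-04), and the falls of Zfp36l2 (−1.03) and Fzr1 (−0.47) were not called. In all, 491 genes rose and 2499 fell among 8474 tested, and the median change of all genes was −0.33. Codes in the peak names place 2 h in 1 series with the untreated libraries and 4 h and 6 h in others, so the changes at 2 h are the ones within a series. The treated lists covered fewer genes, 2693 to 5888 against 6429 to 6690 in untreated lists. Simulated lists with these gene numbers called 729 of 8118 unchanged genes lower, so the number of falls can include genes that a shorter gene list alone makes lower. With 1 rank per gene, an alternative chosen after the data were seen that gives every library the same ranks and so balances rises and falls, 418 genes rose and 626 fell with a median change of 0.04, and 341 of the 491 rises and 626 of the 2499 falls were also called.

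NF-kB primary response genes and negative feedback regulators had the highest medians of the fixed gene lists after R837. Of 29 tested NF-kB primary response genes 28 rose, also adjusted over the list alone, with a median change of 3.97 (camera, adjusted p = 1.12e-42). Negative feedback regulators, some of which are also in the NF-kB list, followed with 16 of 21 rising and 1 falling (median 3.13, adjusted p = 3.75e-19). Among them were Tnip1 (3.92 ± 0.36) and Il1rn (3.99 ± 0.42). Among 19 secondary cytokine and effector genes 13 rose, 15 adjusted over the list alone (median 1.37, adjusted p = 4.6e-18), including Ccl5 (5.65 ± 0.32) and Acod1, the itaconate-producing enzyme (5.71 ± 0.42). Interferon-stimulated genes rose in 13 of 25 cases, 14 adjusted over the list alone (median 1.14, adjusted p = 1.48e-15), such as Isg15 (3.82 ± 0.42), Usp18 (3.44 ± 0.41) and Irf7 (2.63 ± 0.37). Glycolysis and hypoxia genes rose in 9 of 20 cases, also adjusted over the list alone (median 0.75, adjusted p = 2.86e-09), with Pfkfb3 at 5.43 ± 0.40 and the glucose transporter gene Slc2a1 at 2.27 ± 0.33. These 5 lists kept their calls with an estimated correlation.

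Components of the TLR, IKK and caspase-8 pathways went both ways. Of 34 tested, 7 rose and 5 fell, the same counts adjusted over the list alone (median 0.10, adjusted p = 4.79e-04, and adjusted p = 0.0728 with an estimated correlation). Ikbke, which encodes an IkB kinase relative, rose by 4.24 ± 0.36, Cflar, a regulator of caspase-8, by 3.77 ± 0.39 and the adaptor gene Myd88 by 2.02 ± 0.38. Tab1 changed by −2.93 ± 0.42 and the kinase gene Ripk1 by −2.34 ± 0.44. Antigen presentation genes rose in 3 of 10 cases and fell in 1, with 4 and 1 adjusted over the list alone (median 0.54, adjusted p = 0.00448, and adjusted p = 0.0871 with an estimated correlation). The rises were 5 without replicate 1 of KO at 6 h and 1 without replicate 2 of KO untreated. The fall was lost without any of 11 libraries, all but replicate 1 of WT untreated (2 falls), KO untreated, KO 2 h, WT 6 h and KO 6 h. Ribosomal protein genes had a median of −0.01 and a mean of −0.05 with 0 rises and 3 falls among 36, 0 and 0 adjusted over the list alone, and there was 1 fall without replicate 2 of WT or of KO untreated. Camera placed that list above other genes (adjusted p = 0.0217, and adjusted p = 0.149 with an estimated correlation).

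Lysosomal genes fell in 13 of 21 cases, 14 adjusted over the list alone, with a median of −0.84 (adjusted p = 0.00415, and adjusted p = 0.0871 with an estimated correlation). Psap, the precursor of the saposins, changed by −5.66 ± 0.33 and the proton pump gene Atp6v1a by −2.69 ± 0.35. Macrophage identity genes did not move together: 14 of 30 fell, such as Gpnmb (−5.66 ± 0.31) and Apoe (−3.33 ± 0.26), and 7 rose, such as Msr1 (3.17 ± 0.40) and Cd14 (2.63 ± 0.34), the same counts adjusted over the list alone (adjusted p = 0.834). The remaining lists did not pass. Cell cycle genes had 0 rises and 9 falls of 20, 10 falls adjusted over the list alone (adjusted p = 0.137, and 0.0434 without WT untreated replicate 2). The others were oxidative phosphorylation (0 and 8 of 23, adjusted p = 0.327), sterol synthesis and uptake (0 and 4 of 16, adjusted p = 0.982), the unfolded protein response (1 and 4 of 17, adjusted p = 0.735), immediate early genes (2 and 5 of 18, adjusted p = 0.735) and NRF2 targets (3 and 2 of 12, adjusted p = 0.11). These 5 had the same counts adjusted over the list alone. Without replicate 2 of WT untreated the falls were 4 for oxidative phosphorylation and 2 for the unfolded protein response, which had 2 rises without replicate 1 of KO at 6 h. Immediate early genes had 1 rise without replicate 1 of KO untreated, and NRF2 targets 1 fall without replicate 2 of that group. The NRF2 list had a mean of 0.11 and a median of −0.11, and camera placed immediate early and sterol genes above other genes although their medians were −0.25 and −0.10. Falls in these lists carry the limit given above for all falls, and with 1 rank per gene the lysosomal list passed with 7 falls (adjusted p = 4.09e-04).

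In WT macrophages the largest rises at 2 h were those of Socs3 (10.14 ± 0.64), Icam4 (8.72 ± 0.57, summit shared with the adhesion gene Icam1 in 12 of 13 libraries), Ccl4 (8.69 ± 0.81), Ccl3 (8.63 ± 0.82) and Ehd1 (8.42 ± 0.62). At 4 h they were Ccl3 (11.03 ± 0.82), Ccl4 (11.03 ± 0.81), Socs3 (9.13 ± 0.64), Saa3 (8.22 ± 2.37) and Pde4b (7.77 ± 0.76). At 6 h they were Socs3 (9.41 ± 0.64), Ccl3 (9.26 ± 0.82), Ccl4 (9.24 ± 0.81), Saa3 (9.23 ± 2.37) and Pde4b (7.57 ± 0.76). The largest falls in WT were those of Zfp36l2 (−8.71 ± 0.73, −8.90 ± 0.73 and −9.10 ± 0.73 at 2, 4 and 6 h), Rgs2 (−8.15 ± 0.49, −8.28 ± 0.49 and −8.28 ± 0.49), Ctsd at 2 h (−8.69 ± 0.53) and the small GTPase gene Rhob at 4 and 6 h (−7.20 ± 0.62 and −7.33 ± 0.62). The change of Ctsd at 2 h was 0.74 when summits were counted.

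In WT, 299 genes rose and 1111 fell at 2 h, 298 and 924 at 4 h, and 263 and 1191 at 6 h. With 1 rank per gene the counts were 304 and 310, 263 and 283, and 277 and 325. The WT totals of 1410, 1222 and 1454 dropped to 694 and 595 without replicate 1 or 2 of the 2 h group, to 598 and 701 without those of the 4 h group, and to 888 and 656 without those of the 6 h group. With only the compared groups in the limma fit 0 genes passed at each time (2305, 1942 and 2109 at an unadjusted p under 0.05). Differences between times were not tested.

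In KO macrophages the largest rises at 2 h were those of Socs3 (9.09 ± 0.64), Icam4 (8.48 ± 0.57), Cxcl1 (8.45 ± 0.72), Icam1 (8.26 ± 0.72, summit shared in 8 of 16 libraries) and Ccl4 (8.03 ± 0.81). At 4 h they were Saa3 (10.29 ± 2.37), Socs3 (9.81 ± 0.64), Ccl4 (9.58 ± 0.81), Ccl3 (9.32 ± 0.82) and Cxcl2 (8.40 ± 0.78). At 6 h they were Socs3 (10.14 ± 0.64), Ccl4 (8.68 ± 0.81), Cxcl2 (8.17 ± 0.78), Ier3 (8.07 ± 0.88, summit shared with Flot1 in 1 of 16 libraries) and Tnfaip3 (7.85 ± 0.63). The largest falls in KO were those of Zfp36l2 (−9.03 ± 0.73, −8.53 ± 0.73 and −9.10 ± 0.73 at 2, 4 and 6 h), of Fzr1 with the shared summit of Mfsd12 (−7.44 ± 0.61, −8.46 ± 0.61 and −8.04 ± 0.61) and of Rgs2 at 2 h (−7.04 ± 0.49). The change of Fzr1 at 6 h was 0.24 when summits were counted.

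In KO, 223 genes rose and 830 fell at 2 h, 321 and 778 at 4 h, and 434 and 939 at 6 h. With 1 rank per gene the counts were 223 and 257, 241 and 274, and 335 and 360. The KO total of 1053 at 2 h dropped to 574 without replicate 2 of that group, and the total of 1099 at 4 h to 647 and 644 without replicate 1 or 2. With only the compared groups in the limma fit 0, 15 and 0 genes passed (1868, 1973 and 2048 at an unadjusted p under 0.05). The limit on falls applies to these counts and to those in WT.

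After R837, KO macrophages had higher polymerase ranks than WT at some chemokine genes, such as Cxcl1 and Ccl5, and lower ranks at others, such as Ccl7 and Ccl2. Cxcl1, a neutrophil chemokine gene (gene ID 14825, chromosome 5, 90891245 to 90893121), was 4.16 ± 0.41 higher in KO over the 3 treated times (6 against 6 libraries, adjusted p = 5.14e-04), and Ccl5 (gene ID 20304, chromosome 11, 83525778 to 83530518) was 3.22 ± 0.32 higher (adjusted p = 5.14e-04). Slc7a11, the cystine transporter gene (gene ID 26570, chromosome 3, 50364936 to 50499087), was 2.73 ± 0.33 higher (adjusted p = 0.00232), with a summit in 5 of 6 treated KO lists and 1 of 6 WT lists. Fcgr1, the high-affinity IgG receptor gene (gene ID 14129, chromosome 3, 96282909 to 96293969), was lower in KO by −3.77 ± 0.35 (adjusted p = 5.14e-04), and Il4ra, the interleukin-4 receptor gene (gene ID 16190, chromosome 7, 125552271 to 125579474), by −3.27 ± 0.35 (adjusted p = 8.69e-04). The monocyte chemokine genes Ccl7 and Ccl2 were lower by −2.89 ± 0.34 and −2.45 ± 0.43.

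**Figure D2:**
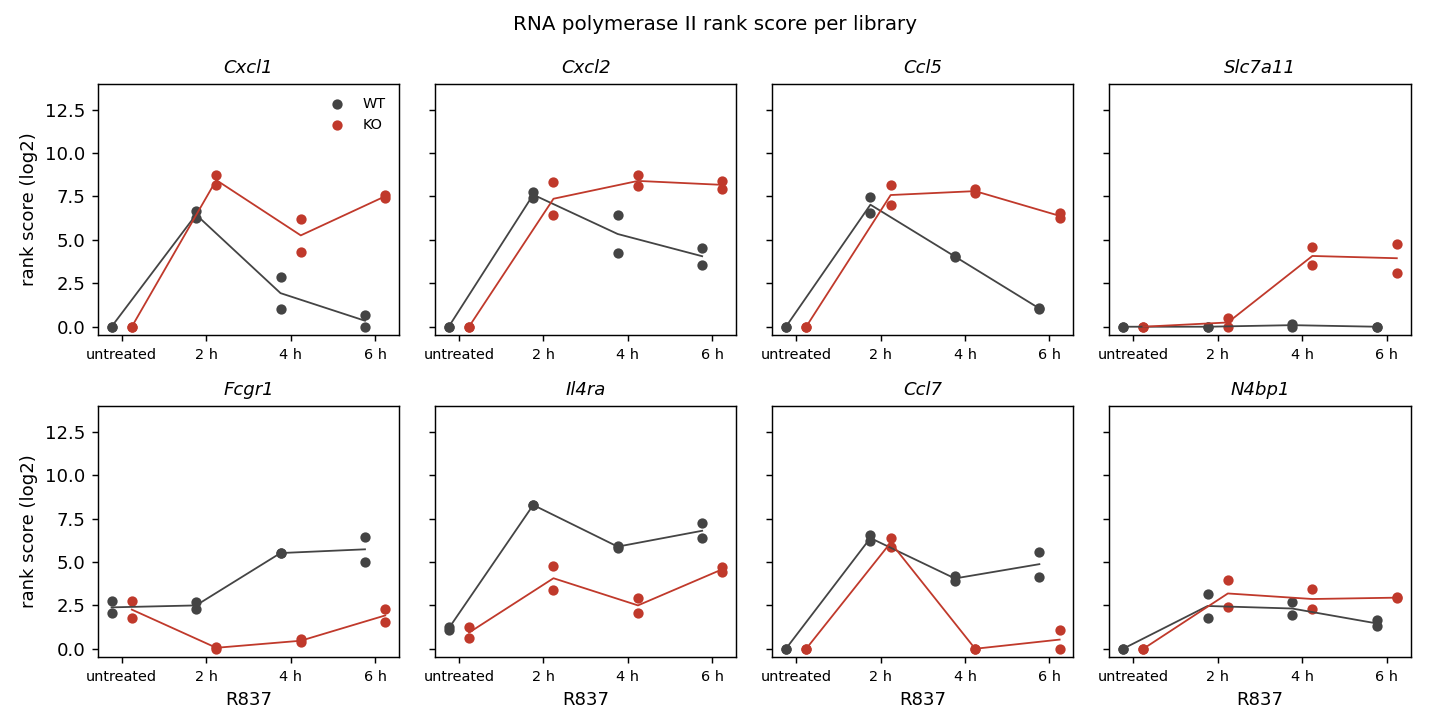
Rank score (log2, vertical axis) of 8 genes against treatment, with 1 point per library and a line through the means of the 2 libraries of each group (WT grey, KO red). The scores of Cxcl1, Cxcl2, Ccl5 and Slc7a11 were higher in KO at 6 h, those of Fcgr1 and Ccl7 were lower in KO at 4 and 6 h, and N4bp1 did not differ past the test at any time.

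Other genes higher in KO were Esd (2.68 ± 0.40), the lectin receptor gene Clec4e (2.42 ± 0.38), Cxcl2 (2.31 ± 0.45), the signalling adaptor gene Traf1 (2.24 ± 0.28), Rpl30 (2.11 ± 0.42), Ifi205 (2.03 ± 0.35), the prostaglandin synthase gene Ptgs2 (2.02 ± 0.41) and the urokinase receptor gene Plaur (1.93 ± 0.37). Other genes lower in KO were the lipoprotein lipase gene Lpl (−2.69 ± 0.49), Zc3h12d (−2.49 ± 0.36), Fzr1 (−2.44 ± 0.35, summit shared with Mfsd12) and Spef1l (−2.40 ± 0.37, summit shared with Adam8). In all, 39 genes were higher and 25 lower in KO, against 17 and 30 with 1 rank per gene, of which 14 and 20 were shared with the first count. The count depends on single libraries: without replicate 1 of KO at 6 h it was 279 and 45, without replicate 2 of WT at 6 h 11 and 28, and without replicate 1 of WT at 2 h 7 and 11. Totals were 26 without replicate 2 of WT at 2 h, 28 without replicate 1 of KO at 2 h, 42 without replicate 1 of WT at 4 h, 42 without replicate 2 of KO untreated and 112 without replicate 2 of KO at 6 h. Of the 20 genes that the naming rule took 11 passed whichever library was left out, Cxcl1, Ccl5, Slc7a11, Esd, Traf1, Fcgr1, Il4ra, Ccl7, Zc3h12d, Fzr1 and Spef1l. Among the others, Cxcl2 and Rpl30 reached adjusted p = 0.107 and 0.118 without replicate 1 of WT at 2 h, Ptgs2 0.125, Plaur 0.107, Lpl 0.0899, Ccl2 0.081 and Clec4e 0.054, and Ifi205 reached 0.0754 without replicate 2 of that group. When summits were counted instead of ranked, the values of Cxcl1, Cxcl2, Ccl5 and Ptgs2 were −0.10, −0.33, −0.47 and −1.10, of which that of Ccl5 passed in this opposite direction (adjusted p = 0.00244), and 4 of the 20 genes passed in the same direction as with ranks. With gene ends only the value of Ccl5 was −0.35 (adjusted p = 1). That setting also lost the calls of Traf1 (1.74, adjusted p = 0.0953), Zc3h12d (−0.64, adjusted p = 0.61), Cxcl2 (adjusted p = 0.0516) and Rpl30 (adjusted p = 0.051). With a linear rank 14 of the 20 lost their call, among them Cxcl1 (adjusted p = 0.0746), Ccl5 (0.0781), Esd (0.138), Il4ra (0.348) and Zc3h12d (0.0511).

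Grouped by the fixed lists, the treated KO macrophages had higher ranks at NF-kB primary response genes and lower ranks at interferon-stimulated and macrophage identity genes. Of 29 NF-kB genes 6 were higher in KO, 12 adjusted over the list alone (Cxcl1, Traf1, Clec4e, Cxcl2, Ptgs2 and Tnfaip3 among them), with a median of 0.69 (camera, adjusted p = 4.39e-06, and adjusted p = 0.0412 with an estimated correlation). Of 25 interferon-stimulated genes 2 were lower, Oas3 (−2.17 ± 0.34) and Rsad2 (−1.22 ± 0.24), and 8 adjusted over the list alone, with a median of −0.56 (adjusted p = 5.55e-12, and adjusted p = 0.00529 with an estimated correlation). Of 30 macrophage identity genes 2 were lower, Fcgr1 and Lpl, and 10 adjusted over the list alone, with a median of −0.77 (adjusted p = 1.55e-16, and adjusted p = 6.44e-04 with an estimated correlation). NRF2 targets had a median of 0.63 with 1 member higher, Slc7a11, and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.00119, and adjusted p = 0.0284 with an estimated correlation). The numbers of members passing over all genes depend on single libraries. For the NF-kB list the 6 became 2 without WT 2 h replicate 1. They became 3 without replicate 2 of WT or KO at 2 h, replicate 1 of WT or KO at 4 h, replicate 2 of WT at 6 h or any untreated library. For the interferon list the 2 became 0 without WT 2 h replicate 1 and 4 without WT 4 h replicate 2. They became 1 without WT 2 h replicate 2, WT untreated replicate 2 or any library of KO 2 h, KO 4 h, WT 6 h or KO untreated. For macrophage identity the 2 became 4 without KO 6 h replicate 1. They became 1 without replicate 1 of WT 2 h, KO 2 h or KO 4 h or any library of WT 4 h or KO untreated. For NRF2 targets the 1 became 3 and 2 without replicates 1 and 2 of KO 6 h and 2 without WT 2 h replicate 2. The NF-kB list was not called when summits were counted instead of ranked (median 0.06, adjusted p = 0.732), nor was the NRF2 list (adjusted p = 0.844), which also lost its call with gene ends only (adjusted p = 0.0752).

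Of the other lists, ribosomal protein genes had a median of 0.60 with 0 of 36 passing in limma, 12 of them higher at an unadjusted p under 0.05 (camera, adjusted p = 0.00204, and adjusted p = 0.0952 with an estimated correlation). That call was lost without replicate 1 of KO at 6 h (adjusted p = 0.106) and with the lists as deposited (adjusted p = 0.177). Antigen presentation genes had a median of −0.05 (adjusted p = 0.038, and adjusted p = 0.244 with an estimated correlation), and the call was lost with 1 rank per gene (adjusted p = 0.101) and without any of 8 libraries. These were WT untreated replicates 1 and 2 (adjusted p = 0.0538 and 0.0545), WT 2 h replicate 1 (0.101), KO 2 h replicate 2 (0.0635), WT 4 h replicate 1 (0.141), KO 4 h replicate 2 (0.0751), WT 6 h replicate 1 (0.0864) and KO 6 h replicate 1 (0.0766). Secondary cytokine genes went both ways, with Ccl5 and Lcn2 (1.06 ± 0.18) higher and Ccl7, Il10 (−2.29 ± 0.40) and Ccl2 lower, and 9 higher and 4 lower adjusted over the list alone (adjusted p = 0.481, and 0.0015 without KO 6 h replicate 2). The counts over all genes were 4 higher and 5 lower, and 5 and 4, without replicates 1 and 2 of KO 6 h, and 1 and 1 without KO 2 h replicate 1 or either WT library of 2 h. Negative feedback regulators had 1 member higher, Tnfaip3 (1.73 ± 0.36), also in the NF-kB list, and 1 lower, Il10, also in the secondary cytokine list. Adjusted over the list alone they had 3 and 1 (camera, adjusted p = 0.619). At least 1 of these 2 calls was lost without any of 13 libraries, all but KO 4 h replicate 2 and both of KO 6 h. The TLR, IKK and caspase-8 list had a median of 0.37 and 0 members passing in limma, 5 of them higher at an unadjusted p under 0.05 (adjusted p = 0.0957). It passed without KO 2 h replicate 2 (adjusted p = 0.0351), WT 2 h replicate 2 (0.038) or KO 6 h replicate 2 (0.0275). The adjusted p was 0.481 for cell cycle and for lysosome, 0.555 for glycolysis and for the unfolded protein response, 0.474 for immediate early genes, 0.619 for oxidative phosphorylation and 0.485 for sterol synthesis. Adjusted over the list alone, 1 unfolded protein response gene was higher and 1 sterol gene lower. The cell cycle, lysosome, immediate early, sterol and negative feedback lists had medians above 0, from 0.03 to 0.13, while camera placed them below other genes.

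Markers of other cell types were nearly absent from the lists. Of 75 markers in 7 lists 6 could be tested, 3 for T and NK cells, 2 for dendritic cells and 1 for neutrophils, and none of the B cell, mast cell, erythroid or stromal markers reached 2 lists. In limma 0 of the 6 differed between treated KO and WT macrophages, and Flt3 (0.13 ± 0.06) was below 0.05 before adjustment. The T and NK cell list had adjusted p = 0.94 for that difference and 0.834 for R837, and the 1 neutrophil gene changed by 0.29 with R837. With R837, Xcr1 rose by 2.34 ± 0.48 and Il7r changed by −0.84 ± 0.17.

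The difference between KO and WT at the NF-kB list passed at 4 and 6 h. Its median was −0.17 at 2 h (adjusted p = 0.173), 1.37 at 4 h (adjusted p = 1.7e-11, and adjusted p = 0.00759 with an estimated correlation) and 1.25 at 6 h (adjusted p = 8.67e-05, and adjusted p = 0.0946 with an estimated correlation). At 4 h 1 of 29 members was higher in KO over all genes. At 6 h 7 of 29 members were higher in KO, 10 adjusted over the list alone, including Clec4e (3.23 ± 0.65) and Tnfaip3 (3.51 ± 0.63), and the list's call was lost without replicate 1 of KO at 6 h (adjusted p = 0.091). The 7 became 2 without replicate 2 of KO or WT at 6 h and 3 without replicate 1 of WT. Interferon-stimulated genes had medians of −0.11 at 2 h (adjusted p = 3.45e-05, and adjusted p = 0.0605 with an estimated correlation), −1.01 at 4 h (adjusted p = 6.04e-16) and 0.03 at 6 h (adjusted p = 0.614). At 2 h 1 of 25 members was lower in KO over all genes. At 4 h 5 of 25 members were lower in KO, Ifit3 (−1.89 ± 0.26), Rsad2 (−2.54 ± 0.41), Ifit2 (−2.81 ± 0.49), Oas3 (−3.03 ± 0.59) and Oasl1 (−2.49 ± 0.48). The 5 became 2 without any library of WT 2 h, KO 2 h or KO untreated or replicate 1 of KO 4 h. They became 3 without replicate 2 of KO 4 h or KO 6 h. Macrophage identity genes had medians of −0.38 at 2 h (adjusted p = 2.49e-04, and adjusted p = 0.0605 with an estimated correlation), −0.93 at 4 h (adjusted p = 2.75e-09) and −0.72 at 6 h (adjusted p = 1.82e-10).

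Among the other lists at single times, NRF2 targets had medians of 0.97 at 4 h (adjusted p = 0.0185, and adjusted p = 0.0808 with an estimated correlation) and 1.23 at 6 h (adjusted p = 6.46e-04, and adjusted p = 0.0305 with an estimated correlation). The first call was lost without replicate 2 of KO or WT at 4 h (adjusted p = 0.215 and 0.0652) and the second without replicate 1 of KO at 6 h (adjusted p = 0.11). Ribosomal protein genes had medians of 0.42 at 2 h (adjusted p = 0.00714, and adjusted p = 0.169 with an estimated correlation) and 0.56 at 4 h (adjusted p = 0.00216, and adjusted p = 0.0901 with an estimated correlation). These calls were lost without replicate 2 of KO or WT at 2 h (adjusted p = 0.413 and 0.214) and without replicate 2 of KO at 4 h (adjusted p = 0.179). Antigen presentation genes had medians of −0.73 at 2 h (adjusted p = 0.00601, and adjusted p = 0.169 with an estimated correlation) and −0.70 at 4 h (adjusted p = 0.0191, and adjusted p = 0.182 with an estimated correlation). Their calls were lost without replicate 2 of KO or 1 of WT at 2 h (adjusted p = 0.112 and 0.116) and at 4 h (adjusted p = 0.119 and 0.211). No list was called between untreated KO and WT macrophages, where the lowest adjusted p was 0.104. Differences between times were not tested.

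**Figure D3:**
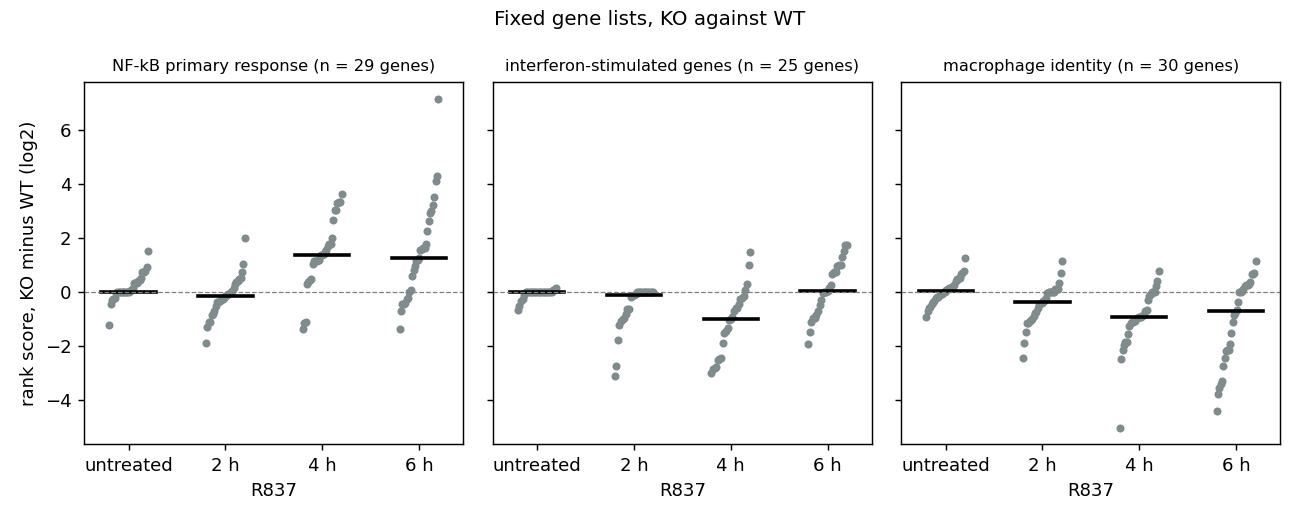
Change in rank score (log2, KO minus WT, vertical axis) of each tested member of 3 fixed gene lists against treatment, with 1 point per gene in order of size and a bar at the median. Medians of the NF-kB list were 1.37 at 4 h and 1.25 at 6 h, and those of the macrophage identity list −0.93 and −0.72.

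At single times several of the same genes had the largest differences between KO and WT. At 2 h the only gene higher in KO was Gpr132 (0.96 ± 0.12), and the lowest values were those of Il4ra (−4.22 ± 0.61, and 1.35 with adjusted p = 0.00677 when summits were counted) and Cxcl10 (−3.14 ± 0.47, summit shared with Art3). The other 2 genes lower in KO, named after their values were seen, were Arhgef17 (−2.20 ± 0.25) and Sytl3 (−1.14 ± 0.18). At 4 h Slc7a11 (3.98 ± 0.57), Ccl5 (3.77 ± 0.56), Traf1 (3.62 ± 0.48), Ifi205 (3.20 ± 0.61) and Clcn7 (2.79 ± 0.51, summit shared with Ccdc154 in 1 of 15 libraries) were higher, and Fcgr1 (−5.05 ± 0.60), Ccl7 (−4.05 ± 0.59) and Glipr1 (−4.02 ± 0.62) lower. At 6 h Cxcl1 (7.17 ± 0.72), Ccl5 (5.33 ± 0.56), Ptgs2 (4.31 ± 0.71), Plaur (4.12 ± 0.65) and Cxcl2 (4.11 ± 0.78) were higher, and Lpl (−4.41 ± 0.85), Ccl7 (−4.34 ± 0.59) and C3ar1 (−4.20 ± 0.77) lower. When summits were counted, the 6 h values of Ccl5, Ptgs2, Cxcl2 and C3ar1 took the other sign (−1.40, −1.72, −0.61 and 0.42), and that of Ccl5 passed there (adjusted p = 5.43e-05).

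Between KO and WT 1 gene was higher and 5 lower at 2 h, 14 and 20 at 4 h, and 96 and 17 at 6 h, against 12 and 22, 18 and 27, and 64 and 49 with 1 rank per gene. Called in both were 0 and 4, 6 and 9, and 35 and 15. The 6 h count fell to 23 and 42 without replicate 2 of WT and to 41 and 27 without replicate 1 of WT, and was 566 and 51 without replicate 1 of KO. At 4 h totals were 57 without replicate 2 of WT, 78 and 84 without replicate 1 or 2 of KO, 22 without either WT library of 2 h and 52 without replicate 1 of KO at 6 h. At 2 h they were 20 without either WT library, 15 and 58 without replicate 1 or 2 of KO, 3 without either WT library of 6 h and 13 without replicate 2 of KO at 6 h. These counts rest on 2 libraries per group and on a spread shared by all groups, and with only the compared groups in the limma fit 0 genes passed at each of these times (233, 470 and 496 at an unadjusted p under 0.05).

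Cxcl1, Cxcl2, Ccl5, Ccl7 and Socs3 held no summit in the shortened lists of untreated KO or WT macrophages. Atp6v1c1, a proton pump subunit gene (2.64 ± 0.55), Letmd1 (2.55 ± 0.57, and −0.37 when summits were counted), Ankrd10 (2.10 ± 0.40), Pkd1 (1.91 ± 0.42) and Taf6 (1.58 ± 0.26, summit shared with Cnpy4) were higher in KO. Znrd2 (−2.68 ± 0.58, summit shared with Fam89b in 9 of 13 libraries), the transcription factor gene Tal1 (−2.65 ± 0.57) and Slx1b (−2.45 ± 0.53, summit shared with Bola2) were lower. In all, 56 genes were higher and 63 lower, against 17 and 23 with 1 rank per gene. Only 9 of the 56 and 7 of the 63 could be tested with 1 rank per gene, and 3 and 3 were called in both. With the filter at 4 libraries 15 passed, and with only the compared groups in the limma fit 0 did (505 at an unadjusted p under 0.05). Without 1 of the 4 untreated libraries, which leaves a lone library assumed to vary like the other groups, the totals were 475, 435, 378 and 375 (replicates 1 and 2 of WT, then of KO). Without replicates 1 and 2 of WT at 2 h they were 78 and 77, and without those of WT at 6 h 77 and 76.

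The response to R837 itself differed between genotypes at 76 genes, 45 with a positive and 31 with a negative difference (change in KO minus change in WT). Cxcl1 and Ccl5, which held no summit in the shortened untreated lists, differed by 4.16 ± 0.83 and 3.22 ± 0.64 (both adjusted p = 0.0382). For these genes this is the same difference as that between treated KO and WT, with a larger SE. Tal1 differed by 3.19 ± 0.66 and the pair Cox16 and Gm20498, a predicted gene with the same summit, by 3.06 ± 0.63. Tal1 was already lower in untreated KO than in untreated WT macrophages, so its value comes in part from the untreated libraries. Fcgr1 differed by −3.64 ± 0.69, Fzr1 by −3.72 ± 0.70 and Evi2a, which shares its summit with Evi2 and Nf1, by −2.80 ± 0.59. Macrophage identity genes had a median difference of −0.75 (camera, adjusted p = 2.02e-04, and adjusted p = 0.0541 with an estimated correlation) and interferon-stimulated genes of −0.51 (adjusted p = 0.00361, and adjusted p = 0.245 with an estimated correlation). Without WT untreated replicate 2 both lists lost their call (adjusted p = 0.0588), and without KO untreated replicate 1 the interferon list did (adjusted p = 0.0923). With 1 rank per gene 1 gene passed, Kif11, a mitotic kinesin gene (1.80, adjusted p = 0.0322), which is named after its value was seen. Totals without 1 library were 446 and 374 (replicates 1 and 2 of WT untreated), 301 and 318 (KO untreated), 14 and 21 (WT 2 h), 12 and 29 (KO 2 h), 27 and 28 (WT 4 h), 30 (replicate 1 of KO 4 h), 11 and 10 (WT 6 h), and 178 and 126 (KO 6 h). Each of the 8 named genes lost its call without at least 8 of the 16 libraries. The highest adjusted p was 0.0827 for Cxcl1, 0.0791 for Ccl5, 0.0794 for Tal1, 0.0832 for Cox16 and Gm20498, 0.0786 for Fcgr1 and 0.0919 for Evi2a without WT 2 h replicate 2, and 0.077 for Fzr1 without WT 2 h replicate 1. When summits were counted, Cxcl1 and Ccl5 differed by −0.10 and −0.47, and with gene ends only Ccl5 differed by −0.35. The NF-kB list had a median difference of 0.56 and did not pass (camera, adjusted p = 0.0782), except without KO 4 h replicate 2. The lysosomal list did not pass either (camera, adjusted p = 0.0784). It was called below other genes without WT untreated replicate 1, KO untreated replicate 2 or WT 6 h replicate 1.

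Several genes commonly read as markers of macrophage activation did not pass. Il6 had a summit in 2 of 16 shortened lists, both from KO (rank 7378 at 4 h and 2336 at 6 h), with a change after R837 of 0.17 ± 0.22 (adjusted p = 0.575). Il12b changed by 1.21 ± 0.50 (adjusted p = 0.0753) and Nos2 by 1.06 ± 0.42 (adjusted p = 0.0675). Csf3 had a summit in both KO lists of 6 h alone (0.82 ± 0.12 over WT, adjusted p = 0.00663, summit shared with Med24 in 1 of 2). Only these 2 lists brought Csf3 past the filter, and all other lists scored 0 and added no spread. Its value lies near the floor, and the filter at 4 libraries would leave it out, so this call carries little weight. Between treated KO and WT the differences were 0.34 ± 0.22 for Il6, 1.37 ± 0.50 for Il12b, 0.27 ± 0.07 for Csf3, 0.56 ± 0.42 for Nos2, 0.17 ± 0.49 for Il1b, 0.82 ± 0.43 for Tnf and 0.02 ± 0.49 for Nfkbia, none of which passed. Actb, a housekeeping gene, changed by 0.01 ± 0.51 after R837 (adjusted p = 0.994) and by −0.07 ± 0.51 between treated KO and WT (adjusted p = 1). Within genotypes, Tnf, Nfkbia and Cxcl2 rose at all 3 times in WT and KO, by 5.24 to 7.28, 5.05 to 8.42 and 4.06 to 8.40. When summits were counted, Nfkbia changed by −0.49 at each time in KO and by −0.74 in WT at 4 h. Il1b and N4bp1 rose at 5 of these 6 times, with 1.33 ± 0.85 for Il1b in KO at 2 h and 1.46 ± 0.66 for N4bp1 in WT at 6 h not passing. Csf3 passed in KO at 6 h, with the limit given above, and Il6, Il12b, Nos2 and Actb at none. Between KO and WT at single times Cxcl2 and, with the same limit, Csf3 passed at 6 h. None of these 10 genes passed for the difference in response.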

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

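All tests of explanations in this part were chosen after the results were seen. The test of the response itself, R837 against untreated in KO minus the same in WT, passed at 76 genes, and it is this difference between genotypes that set these results apart. Cxcl1 differed by 4.16, Ccl5 by 3.22, Tal1 by 3.19 and the pair Cox16 and Gm20498 by 3.06 each. Cxcl1 and Ccl5 held no summit in the shortened untreated lists. Their values are therefore the same as those between treated KO and WT and add no separate evidence. The value of Tal1 comes in part from the untreated libraries, where it was lower in KO than in WT. Fzr1 differed by −3.72, Fcgr1 by −3.64 and Evi2a by −2.80. The medians were −0.51 for interferon-stimulated genes and −0.75 for macrophage identity genes, but neither list passed with an estimated correlation (adjusted p = 0.245 and 0.0541) or without WT untreated replicate 2 (adjusted p = 0.0588 for both). The interferon list also lost its call without KO untreated replicate 1 (adjusted p = 0.0923). None of these 8 genes passed with 1 rank per gene, with array weights, with the lists as deposited, with the filter at 4 libraries or, in the same direction, with the number of summits, where 1, 17, 16, 2 and 270 genes passed in limma (432, 526, 1010, 701 and 735 at an unadjusted p under 0.05).

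More genes were lower than higher after R837, 2499 against 491. In KO at 4 h, where both lists were longer than both untreated lists, 778 genes were lower and 321 higher. This argues against shorter lists as the cause of the excess in that comparison. It crosses series and does not settle the part of list length at the other times. Treated lists of equal length also reached fewer genes, and this stays open, because 1 rank per gene, where 60.0% of the calls were lower, balances rises and falls by construction and cannot decide it. A difference between the series of libraries cannot be told apart from the 4 h and 6 h times. The 2 h libraries are in the series of the untreated ones, and there 299 genes rose and 1111 fell in WT and 223 and 830 in KO. These counts argue against a series difference as the cause at 2 h. Of 100 splits within genotypes, drawn from 784, only the real one (1) gave as many genes in a model of genotype and treatment (2686, highest other 1046). This makes a random split of these libraries an unlikely source of the count. It does not exclude chance, since splits that mix treatments carry any treatment difference in their spread, which lowers their counts. The splits also do not address the number of genes reached.

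At 6 h 96 genes were higher and 17 lower in KO. The shortened KO lists of 6 h reached 4722 and 5888 genes and the WT lists 4390 and 2693. With 1 rank per gene, which balances rises and falls by construction, 64 were higher and 49 lower. Unequal gene numbers therefore stay open as a cause of the excess. Without KO replicate 2, the list with unshared scores, 109 were higher and 10 lower, so more genes were still higher than lower. That fit leaves a lone KO library at 6 h, so it cannot decide whether the score scale of KO replicate 2 contributed, and this stays open. The shortest list, WT replicate 2, may contribute, because without it 23 were higher and 42 lower, but 41 and 27 without WT replicate 1 and 566 and 51 without KO replicate 1 show that each of these libraries moved the count. Each fit without 1 of these libraries leaves a lone library in its group, so the fits do not decide between them. A genotype difference at 6 h stays open beside these explanations.

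In treated macrophages the NF-kB list was higher in KO and the interferon and macrophage identity lists were lower. The setting with 1 rank per gene gives each library the same number of genes. The largest adjusted p of the 3 lists there was 1.95e-07 (camera, preset correlation). At that correlation this argues against unequal gene numbers as the source of the 3 calls. No estimated correlation was combined with this setting, so the part of unequal gene numbers is not settled. The fit without replicate 2 of both 6 h groups leaves a lone library in each of these groups. It cannot decide whether the left-out libraries contributed, and this stays open. The lists were also tested with lists as deposited, the number of summits and gene ends only. Over these 5 alternatives the adjusted p (camera) ranged from 1.95e-07 to 0.732 for the NF-kB list (the latter when summits were counted), from 1.37e-13 to 1.27e-05 for the interferon list and from 7.7e-21 to 8.31e-09 for macrophage identity. An estimated correlation, which is not among the 5, gave the last 2 lists adjusted p-values above these ranges, though both passed. Other cell types in the cultures and the loss of N4bp1 itself both stay open, since only 6 of 75 markers could be tested, of which 0 differed in limma and 1 (Flt3) had an unadjusted p under 0.05.

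The count of 64 genes between treated KO and WT was reached in 1 of 100 splits within times, drawn from 108, the real one, and the highest other count was 23. This makes a random split of these libraries an unlikely source of the count. It does not exclude chance, since splits that mix genotypes carry any genotype difference in their spread, which lowers their counts. With 6 h left out of the contrast 16 genes passed in limma.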

How the results depend on the processing

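The settings 1 rank per gene, replicate 2 of both 6 h groups left out and 6 h left out, the overlap without each library, and all gene list settings but the estimated correlation and replicate block, were chosen after the data were seen. Of 4570 values of 154 gene results under other settings, 3789 kept direction and call, 759 kept direction and lost the call, and 22 reversed. With the filters, no variance trend, array weights, the replicate block and only the groups compared, the change itself stays that of the main fit. It also stays the same where a left-out library lies outside the contrast. Only the call could move there, so these counts overstate how stable the direction is. The reversals came with the number of summits or gene ends only. Depth is unknown, so its limit could not be given. The replicate numbers did not pair the libraries (residual correlations −0.11 to 0.179). Counts below are genes passing, in the order of the contrasts named, and the cause was not tested where they moved.

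Lists of 4197 summits gave 880, 794 and 850 genes in WT at 2, 4 and 6 h, 11 between KO and WT at 2 h and 1742 for R837. Lists as deposited gave 3873, 2167 and 3562 in WT, 2403 in KO at 2 h, 46 between untreated KO and WT, 5392 for R837 and 16 for the response difference, and a gene-end difference of 0.459 points. With 1 rank per gene they were 614, 546 and 602 in WT, 480, 515 and 695 in KO, 40 and 34 between KO and WT untreated and at 2 h, 1044 for R837 and 1 for the response difference. Only the groups compared gave 0, 0 and 0 in WT, 0, 15 and 0 in KO, 0 between KO and WT untreated and at each time, and 104 over the treated times (limma, 2305, 1942, 2109, 1868, 1973, 2048, 505, 233, 470 and 496 at an unadjusted p under 0.05 for the first 10). Array weights gave 751 and 814 in WT at 4 and 6 h, 665 in KO at 6 h, 46, 21 and 80 between KO and WT untreated, at 2 h and at 4 h, 113 over the treated times, 1893 for R837 and 17 for the response difference.

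In 10 kb bins, which are not genes, there were 1685 in KO at 4 h, 226, 57, 169 and 198 between KO and WT untreated and at 2, 4 and 6 h, 146 over the treated times and 139 for the response difference. The filter at 4 libraries gave 15, 3 and 12 between KO and WT untreated, at 2 h and at 4 h, and 2 for the response difference. No variance trend gave 66, 97 and 8 (untreated, treated times, response difference). The number of summits gave 74 and 86 at 2 and 4 h, 263 over the treated times and 270 for the response difference, a linear rank 17 at 2 h and gene ends only 36 over the treated times. A replicate block gave 3 at 2 h, 35 over the treated times and 22 for the response difference, with 0 of the 8 genes named for the latter (adjusted p from 0.0546 to 0.0684). Replicate 2 of both 6 h groups left out gave 771 and 879 in WT and KO at 6 h, and 2 and 122 between KO and WT at 2 h and over the treated times. The latter contrast gave 16 genes with 6 h left out of it. Presence of a summit by Fisher's exact test gave 223 for R837 and 0 for treated KO against WT (40 at an unadjusted p under 0.05), where the smallest p that 6 against 6 libraries allow, 0.00216, could hardly pass adjustment, so this 0 says nothing about stability. Gene lists called for R837 dropped from 9 to 5 with an estimated correlation, for treated KO against WT from 6 to 3 with the number of summits, and for the response difference from 2 to 0 with an estimated correlation and to 1 with the number of summits or without both second 6 h libraries.

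The number of summits reversed C3ar1 (0.42), Ccl5 (−1.40), Cxcl2 (−0.61) and Ptgs2 (−1.72) at 6 h, Il4ra (1.35) at 2 h and Letmd1 (−0.37) untreated, all between KO and WT. Over the treated times it reversed Ccl5 (−0.47), Cxcl1 (−0.10), Cxcl2 (−0.33) and Ptgs2 (−1.10), and for the response difference Ccl5 (−0.47) and Cxcl1 (−0.10). For R837 it reversed Ctsd (1.60, and 0.74 in WT at 2 h), Fzr1 in KO at 6 h (0.24) and Nfkbia (−0.33, −0.49 at each time in KO, and −0.74 in WT at 4 h). Gene ends only reversed Ccl5 over the treated times and for the response difference (both −0.35).

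Without each library in turn the lowest and highest counts were 595 and 1495, 598 and 1383, and 656 and 1550 in WT, 574 and 1292, 644 and 1331, and 932 and 1606 in KO at 2, 4 and 6 h. Between KO and WT they were 76 and 475 untreated, 3 and 58, 22 and 84, and 65 and 617 at 2, 4 and 6 h, and 18 and 324 over the treated times. For R837 they were 2534 and 3030, and for the response difference 10 and 446. The difference in log2 list length was 0.278 to 0.533, in overlap 1.75 to 3.84 points, and in gene-end share 4.14 to 7.65 for KO and −19.6 to −17.7 for R837.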

Other observations

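The overlap counts in this part were chosen after the results were seen, and no explanation was tested for them. Genes higher in treated KO than WT macrophages overlapped with genes that rose after R837: 22 of the 39, Cxcl1, Cxcl2 and Ccl5 among them, rose in both comparisons (2.3 expected, two-sided Fisher's exact test, p = 7.86e-18), and 1 fell (11.5 expected, p = 2.79e-05). Of the 25 genes lower in KO, 12 also rose after R837 (1.4 expected, Fisher's exact p = 3.27e-09), Ccl7 and Ccl2 among them, and 4 fell (7.4 expected, p = 0.187). Both comparisons use the treated libraries, so they are not independent. The expected counts and p-values take them as independent and so do not give the overlap that chance alone would make.

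Many calls were shared between WT and KO macrophages. The genes that rose in both were 171 at 2 h, 187 at 4 h and 158 at 6 h, against 7.9, 11.3 and 13.5 expected from the counts alone, and those that fell in both were 407, 367 and 495, against 108.8, 84.8 and 132. These expected counts take the calls as independent, but the treated lists of both genotypes reached fewer genes, which alone can make common falls. The numbers for falls are therefore not a measure of a shared response. Across 8474 genes, which are not independent replicates, the changes in WT and KO had r = 0.769, 0.728 and 0.719 (rho 0.604, 0.541 and 0.584) at the 3 times.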
